A study of Macrobrachium nipponense with 4 samples.

How the data were processed

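RNA from the hepatopancreas, the digestive gland that combines liver-like and pancreas-like functions, of juvenile oriental river prawns (Macrobrachium nipponense) was sequenced after exposure to nitrite in the rearing water. The labels describe 4 libraries, 1 for each group. An acute pair was sampled at 24 h, with 0 or 26 mg/l nitrite, and a chronic pair at 28 days (4 weeks), with 0 or 6.555 mg/l nitrite. Each library has a sample size of 9 prawns in the labels, which do not say whether the animals were pooled. Prawns of 1.12 ± 0.06 g (the kind of error is not given in the labels) were kept in 12 tanks of 50. One label field calls the chronic pair acute, so the groups were taken from the treatment labels.

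The authors deposited 1 table of whole-number read counts per contig, not normalized. BWA 0.7.8-r455 and HTSeq are named in the submitters' processing notes, with no role, reference or strand setting given, and per the labels' protocols the libraries followed a standard Illumina preparation of RNA with RIN above 8.0. The assembler, the way contigs of different libraries were merged and any filter on contigs are not given in the sources used here. The table has 58871 contig IDs, of which 41811 are numbered mniContig and the others end in a column name. Of these, 3198 end in the name of the acute control, 4115 in that of the chronic control and 5669 in that of the chronic nitrite library, and 4078 end in a name that matches no label. The IDs carry no gene names, and 0 of them matched the 32339 genes of the RefSeq table for assembly ASM1510439v2. The gene lists fixed in advance (antioxidant and detoxification, heat shock, oxygen transport, nitrogen handling, ion transport, digestive enzymes, immunity, apoptosis, lipid, glycolysis, oxidative phosphorylation, ribosomal proteins, muscle, haemocytes and gonad) could therefore not be formed. Several contigs can belong to 1 gene and share its reads, so counts of contigs are not counts of genes.

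Columns were matched to libraries by name alone, which gave the acute control, the chronic control and the chronic nitrite library. One column of values matched no label, was counted as 1 unused column and entered no step. The acute nitrite library was therefore not analysed here, and the planned acute comparison, its overlap with the chronic one and the fit over 4 libraries were not run. There were 46 contigs without a count in the 3 libraries used, which left 58825. Total counts were 21215108 in the acute control, 26366818 in the chronic control and 24818146 in the chronic nitrite library.

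With 1 library per group, the comparisons of pairs have no replicate check and no p-value. Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), and the ratio of the scaled values, in CPM (counts relative to the scaled library total), was given for contigs with at least 1 CPM in at least 1 of the 2 libraries. Its exact 95% interval came from Clopper-Pearson bounds on the share of the 2 libraries' counts, and covers counting error only. A contig was counted as higher or lower when this whole interval lay beyond 2-fold. A count of 0 was replaced by a floor of 3 counts in that library, which makes the ratio a bound at that floor; the counting interval of such a ratio is wider and starts nearer to no change. The floor equals 0.144 CPM in the acute control, 0.129 in the chronic control and 0.105 in the chronic nitrite library. In 20 Poisson simulations with every ratio at 1, which hold counting noise and no differences between animals, at most 2 contigs passed the rule in any comparison. A library was said to stand apart on a contig when both of its intervals against the other libraries passed the rule in 1 direction.

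Tests were possible for 1 library against the other 2, with 1 residual degree of freedom, and used edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p below 0.05 on contigs with at least 1 CPM in at least 2 libraries. In such a fit the lone library is assumed to vary like the others, and the spread is the difference between the other 2 libraries, whatever its source. DESeq2 1.42.0 and limma 3.58.1 (voom) were the other tools. On simulated data, 100 contigs were changed at each fold, all drawn from contigs with a mean well above 1 CPM. Recovery of contigs near 1 CPM was therefore not measured. With counting noise only (dispersion 0), the size rule for chronic nitrite against chronic control recovered 100 of 100 contigs at 4-fold. It also recovered 100 of 100 at 8-fold, with 0 false calls among 22202 contigs. With a dispersion of 0.05, an assumed value, it recovered 95 and 99 of 100, with 157 false calls among 23129 contigs. The simulated data gave both unexposed libraries the same mean for every contig, apart from depth. The real ones also differed in sampling time. The recovery and false calls of the edgeR fit below therefore do not carry over to the real calls. The edgeR fit for chronic nitrite against the 2 unexposed libraries, simulated with the same dispersion of 0.05, recovered 62 of 100 at 4-fold and 98 of 100 at 8-fold, with 1 false call among 21080 contigs.

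The size rule, the filter, the test settings and the rule for named contigs were fixed before the data were examined. That rule names, for each planned comparison, the 2 contigs higher and the 2 lower whose interval bound nearest to no change lies farthest from it. The 3 fits of 1 library against 2, the comparison of chronic nitrite with the acute control and the counts of contigs on which a library stands apart were added once the columns had been seen, and the windows of the log2 ratio with their count minimum once the ratios had been seen. Alternatives covered the scaling (total counts, DESeq2 size factors, upper quartile), the filter, the fold and level of the interval, thinning to the smallest total, leaving out the 10 most abundant contigs of any library, summing isoform IDs, and leaving out contigs named after a library.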

Results

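Hepatopancreas transcriptomes of juvenile oriental river prawns were compared between animals kept for 28 days in water with 6.555 mg/l nitrite, their control at 0 mg/l, and a second control at 0 mg/l sampled at 24 h in the acute experiment. Each group had 1 library, so all differences between pairs of libraries lack a replicate check. The libraries held 21215108 counts (acute control), 26366818 (chronic control) and 24818146 (chronic nitrite). Of 58825 contigs, 56367 had a count in the acute control, 55862 in the chronic control and 56687 in the chronic nitrite library.

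A few transcripts made up most of each library. The single most abundant contig took 22.78% of the counts in the acute control (exact Clopper-Pearson 95% interval for counting error, 22.76 to 22.80), 18.23% in the chronic control (18.21 to 18.24) and 20.91% in the chronic nitrite library (20.89 to 20.93). The 10 most abundant contigs together took 57.2%, 57.6% and 56.8%, and the 100 most abundant took 75.0%, 76.2% and 73.7%, in the same order. The TMM factor was 0.98 for the acute control, 0.88 for the chronic control and 1.15 for the chronic nitrite library.

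The first comparison asked how the hepatopancreas transcriptome differed after chronic nitrite exposure. Among 22600 contigs, 1047 were higher and 396 were lower in the chronic nitrite library than in the chronic control, with the whole counting interval beyond 2-fold. The higher contigs took 2.18% of the counts in the nitrite library and 0.302% in the chronic control. The lower contigs took 1.79% and 5.88%, of which a single contig, mniContig8927 (named after its values were seen), made 0.0757% in the nitrite library and 2.44% in the chronic control. Within the class of contigs reaching 100 CPM in either library, 24 were higher and 47 lower, whereas 794 were higher and 250 lower in the class from 1 to 10 CPM. The direction in the abundant class depended on the scaling, since total counts gave 29 higher and 17 lower. DESeq2 size factors gave 24 and 40, and upper quartile 23 and 52, the direction of TMM.

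The contigs farthest from no change went from near absence to high counts or the reverse. mniContig28255 had 39201 counts (1369 CPM) in the chronic nitrite library, 0 in the chronic control and 6 in the acute control, and was at least 10619-fold higher than the floor of 3 counts in the chronic control (8636-fold at the lower bound of the wider counting interval). mniContig28806 had 6530 counts against 5 and 7 in the chronic and the acute control, a log2 ratio to the chronic control of 10.05 (counting interval 8.83 to 11.68). In the other direction, mniContig7907 had 4 counts in the nitrite library against 3744 in the chronic control, a log2 ratio of -10.17 (-12.05 to -8.81). The acute control also had only 7 counts of mniContig7907, so its high value belonged to the chronic control. mniContig44006 had 0 counts in the nitrite library, 683 in the chronic control and 618 in the acute control, and was, at the floor of 3 counts, at least 280-fold lower than in the chronic control (227-fold at the bound of the interval). The files pair none of these contigs with a gene.

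The split between higher and lower contigs moved with total counts and little with the other scalings. With TMM, 72.6% of the contigs past the rule were higher, and with total counts 86.5% were (1595 higher and 248 lower). The share was 74.7% with DESeq2 size factors and 71.4% with upper quartile. The median log2 ratio of all 22600 contigs was -0.13 after TMM scaling.

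The second comparison set the unexposed libraries of both experiments against each other, which shows how far apart libraries without nitrite lay when sampling time and library differed. Among 23520 contigs, 564 were higher and 1587 lower in the chronic control than in the acute control. This total of 2151 (9.15% of the contigs) was above the 1443 (6.38%) that separated chronic nitrite from its own control, so the chronic nitrite library differed from its control on fewer contigs than the unexposed libraries differed from each other. Of the 1587 lower contigs, 371 had 0 counts in the chronic control. The lower contigs took 7.10% of the counts in the acute control and 0.757% in the chronic control, and the higher ones took 1.84% and 6.78%. Among the higher ones, mniContig8927 alone made 0.0207% of the acute control's counts and 2.44% of the chronic control's.

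mniContig28207 had 4149 counts in the chronic control, 6 in the acute control and 219 in the chronic nitrite library, a log2 ratio between the controls of 9.27 (8.15 to 10.72). mniContig7907 followed with a log2 ratio of 8.90 (7.86 to 10.22). The contigs farthest below were c22114_g1_i1@@CL and c25309_g1_i1@@CL, whose IDs end in the column name of the acute control. The contig c22114_g1_i1@@CL had 8448 counts there, 0 in the chronic control and 1 in the chronic nitrite library, and was, at the floor of 3 counts, at least 3148-fold lower in the chronic control (2560-fold at the bound of the interval). The contig c25309_g1_i1@@CL had 7857 counts in the acute control and 0 in both chronic libraries, and was, at the floor of 3 counts, at least 2928-fold lower in the chronic control (2381-fold at the bound of the interval). Leaving out the 189 contigs with at least 100 counts in the acute control and at most 3 in each chronic library left 1399 lower contigs, and leaving out all contigs named after a library left 981.

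**Figure D1:**
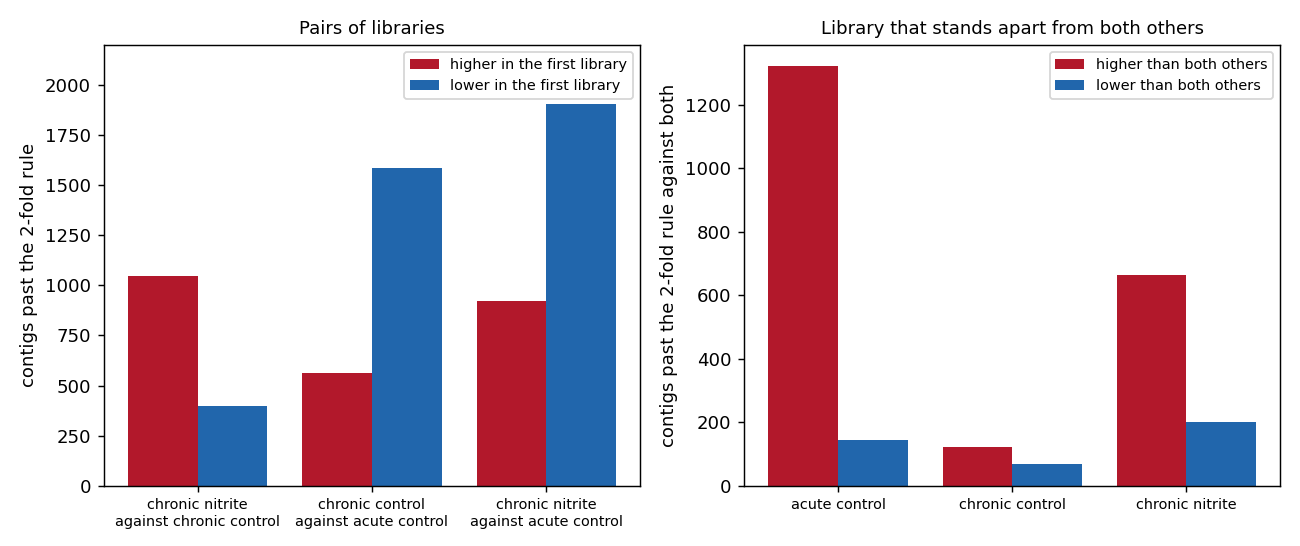
Numbers of contigs past the 2-fold rule (y axes, contigs). The left panel gives contigs higher (red) or lower (blue) in the first library of each pair, and the right panel gives contigs on which 1 library is higher or lower than both others. Chronic nitrite stands apart upwards on 664 contigs, fewer than the 1323 of the acute control and more than the 121 of the chronic control. The chronic libraries share a sampling time and the acute control has its own, so its number is not alike in kind.

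Setting the chronic nitrite library beside both unexposed libraries showed on how many contigs it, or a control, stood apart from both other libraries. It was higher than both controls on 664 contigs and lower than both on 201. The 664 contigs took 1.48% of the counts in the nitrite library, 0.185% in the chronic control and 0.195% in the acute control, and their median log2 ratio was 2.88 to the chronic and 2.70 to the acute control. The 201 contigs took 0.133% of the counts in the nitrite library, 0.665% in the chronic control and 0.669% in the acute control, with median log2 ratios of -3.57 and -3.83, counts of 0 being set to the floor. The chronic control was higher than both other libraries on 121 contigs and lower on 68. The acute control was higher than both on 1323 and lower on 144. It was the only library of its sampling time, whereas each chronic library had to differ from one of the same day. Of the 1047 contigs higher than in the chronic control, 375 passed the rule in neither direction against the acute control and 8 were lower. The chronic control was lower than both others on at most 68 of these, so most of the 375 had no library that stood apart.

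**Figure D2:**
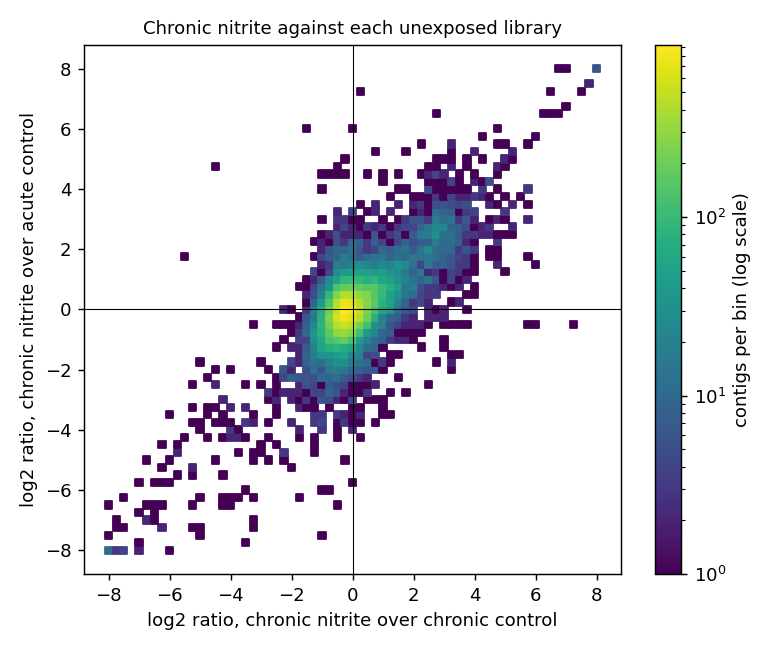
Log2 ratio of chronic nitrite over the chronic control (x axis) and over the acute control (y axis) for the 21356 contigs with at least 1 CPM in both comparisons, coloured by the number of contigs per bin on a log scale, with values beyond 8 drawn at 8. The axes share the nitrite library, so they move together in part by construction. A second group of contigs lies near 2.88 on the x axis and 2.70 on the y axis, the medians of the 664 contigs higher than both controls.

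Well-counted contigs showed a second peak on the higher side. How far it outweighed the ratios below it depended on the count minimum. Among 8965 contigs with at least 200 counts over both chronic libraries and more than 3 in each, a set chosen after the ratios were seen that holds 340 of the 1047 higher contigs, 198 had a log2 ratio to the chronic control from 2.2 to 3.2, against 135 from 1.2 to 2.2. Over all 22600 contigs of the comparison the order was reversed, with 547 from 2.2 to 3.2 and 830 from 1.2 to 2.2. With at least 100 counts the numbers were 286 and 317, and with at least 500 they were 112 and 35. On the lower side of the 8965 contigs, 106 lay from -2.2 to -1.2 and 9 from -3.2 to -2.2.

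**Figure D3:**
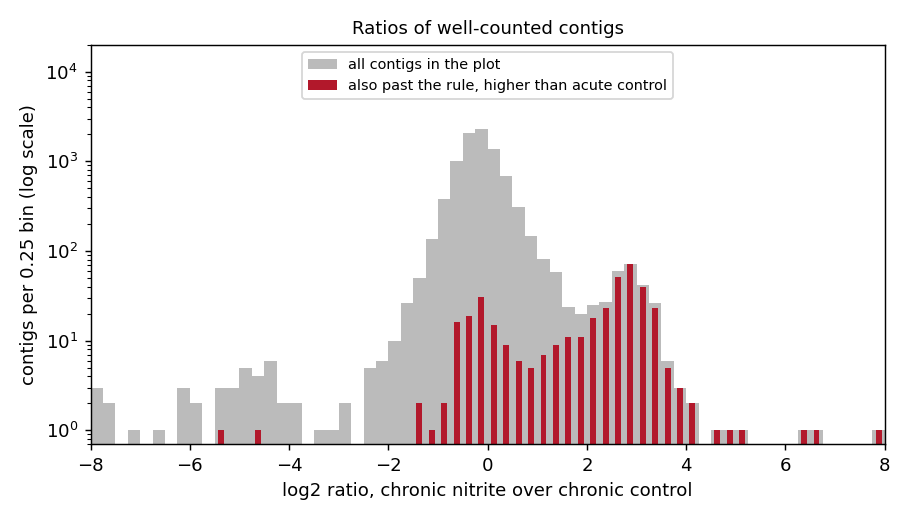
Distribution of the log2 ratio of chronic nitrite over the chronic control (x axis, bins of 0.25) for the same 8965 contigs (grey, contigs per bin on a log scale) and for those also higher than in the acute control (red, a ratio that shares the nitrite library), with values beyond 8 drawn in the end bins. In this set 198 contigs lie from 2.2 to 3.2 and 135 from 1.2 to 2.2, an order that is reversed without the minimum of 200 counts.

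Treating both libraries without nitrite as the unexposed group allowed a test against their spread, which includes their difference in sampling time. With edgeR's quasi-likelihood test (1 exposed library, 2 unexposed, 19905 contigs), 243 contigs rose and 127 fell in the chronic nitrite library at an adjusted p below 0.05. The median log2 fold change was 2.72 for those that rose and -5.95 for those that fell. Both are edgeR's own estimates without the floor of 3 counts, so they are not on the scale of the ratios above. DESeq2 called 217 higher and 125 lower, and limma-voom 217 and 93. Of the 664 contigs higher than in both controls, 310 passed the filter of this test, as did all 201 lower ones. A contig called lower than both controls had at least 1 CPM in each of them, so it passed by construction. A higher one passed only if a control also reached 1 CPM. The number of calls rested on the filter: with contigs at 1 CPM in only 1 library admitted, edgeR called 27 and 40 of 24971, and with no filter 682 and 919 of 58825.

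The other ways of setting 1 library against 2 gave fewer calls at the same filter. This filter needed 1 CPM in at least 2 libraries, so contigs reaching it in the acute control alone could not enter. Of the 1905 contigs lower in chronic nitrite than in the acute control, 1069 lay below 1 CPM in both chronic libraries. For both chronic libraries against the acute control, edgeR called 0 contigs, with 1760 at an unadjusted p below 0.05 and a smallest adjusted p of 0.052, and limma-voom called 0, while DESeq2 called 33 higher and 148 lower. For the chronic control against the other 2 libraries, edgeR called 0, with 408 at an unadjusted p below 0.05, limma-voom called 0, and DESeq2 called 3 higher and 9 lower. With contigs at 1 CPM in only 1 library admitted, the contrast of both chronic libraries with the acute control gave 12 higher and 487 lower by edgeR, against 27 and 40 for nitrite, and with no filter 189 and 1563, against 682 and 919, so at both looser filters the acute control contrast gave the larger total.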

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

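No paired analysis was possible because each group has 1 library, and leaving out a library from a fit of 3 leaves no residual degree of freedom. The acute comparison, the overlap of acute and chronic responses, the fits over 4 libraries and the gene lists were not run. Of the alternative values of counts and shares, 104 stayed within 1.5 times the reported count (or within the counting interval of a share). The other 54 did not. The log2 ratios of the named contigs kept their direction in all 32 alternative values. That outcome was fixed in advance, because the contigs were named for their extreme ratios. For chronic nitrite against chronic control, contigs higher and lower were 1595 and 248 with total counts, 253 and 146 with a 10 CPM filter, 448 and 197 beyond 4-fold, and 2053 and 1201 on the ratio without an interval; contigs lower were 595 without a filter and 986 beyond 1.5-fold. For chronic control against acute control they were 240 and 483 at 10 CPM, 1388 and 2429 beyond 1.5-fold, 77 and 868 beyond 4-fold, and 1992 and 3026 without an interval, with 981 lower when contigs named after a library were left out. Under count minima chosen after the data were seen, with a log2 ratio of chronic nitrite over chronic control from 1.2 to 2.2 there were 830 contigs in all, 317 with at least 100 counts and 35 with at least 500, against 135 with at least 200; from 2.2 to 3.2 there were 547 in all and 112 with at least 500, against 198. Stricter rules give fewer contigs by construction; the cause of the other shifts was not tested. For chronic nitrite against acute control (923 higher and 1905 lower) the numbers were 282 and 627 at 10 CPM, with 1268 lower without contigs named after a library. Contigs on which a library stood apart numbered, at 10 CPM, 216 higher and 70 lower for chronic nitrite, 50 and 16 for the chronic control, and 435 and 57 for the acute control; total counts gave 78 and 114 for the chronic control, and 783 were higher in the acute control without contigs named after a library. In the fits of 1 library against 2, edgeR called 682 higher and 919 lower for nitrite without a filter and 27 and 40 with 1 CPM in at least 1 library. For the chronic pair against the acute control it called 189 and 1563 without a filter and 12 and 487 with 1 CPM in at least 1 library, and DESeq2 called 33 and 148; DESeq2 also called 3 and 9 for the chronic control alone. The cause was not tested beyond the number of contigs admitted. DESeq2 left the adjusted p missing for 4631, 6561 and 3474 of 19905 contigs in the nitrite, acute control and chronic control contrasts. Without contigs under 10 counts over the 3 libraries, the 10 most abundant contigs took 57.2% of the acute control, 57.7% of the chronic control and 56.8% of the nitrite library, and the 100 most abundant 75.1%, 76.2% and 73.8%. At these depths a count of 0 allows up to 0.144 CPM in the acute control, 0.129 in the chronic control and 0.105 in the chronic nitrite library.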

Other observations

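All tests in this part were chosen after the results they measure had been seen. One contig outside the naming rule, mniContig8927, was singled out after its values were seen because it took 2.44% of the chronic control's counts (644379 counts). It took 0.0757% of the chronic nitrite library and 0.0207% of the acute control. Its log2 ratio was -5.40 for chronic nitrite over chronic control (counting interval -5.42 to -5.38), 7.03 for chronic over acute control (6.99 to 7.08), and 1.63 for chronic nitrite over acute control (1.59 to 1.68). It passed the 2-fold rule in all 3 pairs of libraries, at 211 CPM in the acute control, 656 in the chronic nitrite library and 27682 in the chronic control.

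Contigs named after a library differed in how often they were high in it, which was not tested. Of 1343 contigs named after the chronic nitrite library that entered the comparison with the chronic control, 156 were higher and 11 lower, against 824 and 303 of 17975 numbered mniContig. Of 1215 named after the acute control, 9 were higher and 440 lower in the chronic than in the acute control, against 459 and 998 of 18477 numbered mniContig. Of those named after the chronic control, 56 were higher and 45 lower of 1350 in the chronic than in the acute control, and 26 were higher and 39 lower of 1327 in chronic nitrite than in the chronic control.

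The acute control held 189 contigs with at least 100 counts there and at most 3 in each chronic library, 146307 counts or 0.69% of its total, with a median of 329 and a highest count of 8448; the chronic control held 1 such contig and the chronic nitrite library 15. Lower depth of the chronic libraries is argued against by their totals, the smaller being 1.17 times that of the acute control. Allele differences between the prawns were expected to leave about as many contigs nearly missing from the acute control but present in both chronic libraries. These were 3 of 192 (1.56%, exact interval 0.323 to 4.50). They needed at least 100 counts in both chronic libraries, whereas the 189 contigs needed them in the acute control alone. The numbers are thus not alike in kind and cannot decide on allele differences, which stay open. An assembly that kept contigs of every single library alike was expected to give the chronic control a like number, but it had 1 of 190 (0.526%, 0.0133 to 2.90). A contig of the chronic control alone also had to be nearly missing from the chronic nitrite library, sampled on the same day. The acute control had no library of its own sampling time beside it here. These numbers are thus not alike either, and such an assembly stays open. Assembly from the acute control alone stays open. Of the 189 contigs, 70.9% (63.9 to 77.3) have an ID that names that library, against 5.17% of the 23520 compared between the controls. The choice of contigs nearly absent from both chronic libraries favoured such IDs, so the share cannot decide. RNA of another organism in the acute control may be a source. It cannot be told apart from prawn genes active only at 24 h, since the contigs have no names or sequences here. The chronic libraries held 0.0984% of the acute control's counts of them. The choice of contigs kept this share low, so it bears on neither source.

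The 664 contigs higher in the chronic nitrite library than in both unexposed libraries are the pattern closest to the study's question. Scaling or depth is argued against as the source of their number. The lowest number over 3 other scalings and thinning was 655, with 883 under total counts. Leaving out the most abundant contigs gave 760. That setting also let more contigs past the 1 CPM filter (35271 against 22600 for chronic nitrite against chronic control), so it bears little on scaling. Whether the same contigs passed each time was not checked. Assembly from that library alone stays open, since 19.4% (16.5 to 22.6) of these contigs have an ID that names it, against 5.94% of the 22600 contigs compared, and the 74.7% numbered mniContig do not show where they were assembled. With 1 library per group and no gene names, a response to nitrite, a difference in cell makeup and a difference between the sets of prawns sampled all stay open and untested.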
